A study of Homo sapiens with 4 samples.

How the data were processed

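The deposited values are expected counts per gene, not scaled to library size, per the file headers. STAR 2.7.2b, RSEM 1.3.1 and the human genome build GRCh37 are named per the submitters' processing notes, which were available here without the role of each tool, the annotation release or the strand setting. Each sample had 1 table of its own, and groups were taken from the sample titles. Of all values 93.6% were whole numbers, and the expected counts were rounded to whole numbers for the tests. Gene IDs were kept as deposited, and symbols came from the gene name table, which named 39538 of the 57773 IDs. Coordinates were not used, because the reference annotation at hand (GENCODE 29) is of another genome build; it gave only chromosome names, gene order, gene classes, overlaps, GC content and transcript length.

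Genes with enough counts for a test in these group sizes were kept with edgeR's filterByExpr, which left 16090, and 32449 IDs had 0 counts in all 4 libraries. Libraries were scaled with TMM factors, which lay between 0.962 and 1.05. Resistant and untreated libraries were compared with edgeR 4.0.16's quasi-likelihood F-test with robust dispersions, and p-values were adjusted by the Benjamini-Hochberg method over all tested genes. The quasi-likelihood form is the default of this version, settled on as such when the counts of both forms had been seen. The common biological coefficient of variation was 19.6%. A gene was called at an adjusted p below 0.05, and fold changes are log2 with the resistant group over the untreated one, shrunk by a prior count of 2 where CPM were put on a log scale. The standard error of a log2 fold change is its size divided by the square root of its F value, so it belongs to that test. Group values are means ± SD of CPM over 2 libraries. Where a group had 0 counts, the fold was computed against 3 counts over the group and is a lower bound, and with 1 to 3 counts the ratio has an exact 95% conditional binomial interval. R 4.3.3, limma 3.58.1, DESeq2 1.42.0 and mgcv 1.9.3 were also used.

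The 36 gene lists (851 members, 6 of them without a matching ID) and the rules for named genes were fixed before the data were examined, as were the tests apart from the quasi-likelihood form. Lists with at least 5 tested members were tested with limma's camera on log2 CPM with a preset correlation between genes of 0.01, adjusted over the lists. Camera was run again with a correlation estimated from the libraries. That form takes its degrees of freedom from the 4 libraries rather than from the genes, so it had little power to call a list. Fry tested whether a list's genes moved, on balance, one way, without comparing the list with other genes. Named genes were 16 fixed ones, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a symbol, at least 10 CPM in the higher group and no overlap between groups, up to 4 called members per list with the smallest adjusted p and up to 2 members not called with the highest level. Between the resistant populations they were the 5 genes most higher and the 5 most lower in replicate 1, at most 1.5-fold apart between the untreated libraries. Some genes chosen by these rules, and 1 list, are not reported. Genes named outside these rules, among them CDKN2A, ABCB1 and PTPRC, which had too few counts to test, were chosen after their values were seen. Genes that overlap another expressed gene, or that have a near-identical copy, are called uncertain, since the counting may not separate them.

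In simulated counts for 15434 genes with 200 changed, drawn for the comparison of resistant with untreated libraries, the gene test called 8% of genes changed 1.5-fold, 58% at 2-fold, 92% at 4-fold and 98% at 8-fold. Of its 145 calls 17 (11.7%) were unchanged genes, more than the nominal share. Far fewer genes changed in this simulation than were called between the groups (5463 of 16090). Its shares of genes found and of unchanged genes called therefore need not hold for the comparison itself. A list changed 2-fold was called, and 1 of 35 unchanged lists was called. These lists were drawn at random from genes simulated independently, so they do not check the preset correlation where list genes move together. In a simulation of chromosome medians over 12845 protein-coding genes, 0 chromosomes were called with none shifted. With chromosome 11 shifted by 0.4 in log2, 1 was called, the shifted one. Single genes were shuffled for it, which removes the likeness of neighbouring genes. It therefore does not check the error rate where neighbours move together. Alternatives were RLE and upper-quartile scaling, no filter and a stricter one (1 CPM in 2 libraries), a block for the replicate number, each library left out in turn, a threshold of 0.01, DESeq2, limma-voom and edgeR's newer quasi-likelihood form, the last chosen after the data had been seen.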

Results

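Gene expression was measured by sequencing polyadenylated RNA from MIA-PaCa2, a human pancreatic cancer cell line, in untreated cells and in cells resistant to AMG510. AMG510 (sotorasib) is a targeted cancer drug that lowers signalling through the RAF-MEK-ERK kinase cascade. The resistant cells had been grown in rising doses of the drug for 2 months, up to 5 µM, and the labels do not say whether it was present at harvest. Each group held 2 libraries, from populations that the design text describes as 2 resistant and 2 untreated ones. The treatment tag of resistant replicate 2 reads AMG511, whereas its title and the design text name AMG510, and the library was kept in the resistant group. Expected counts summed to 38052558 and 35747414 in untreated replicates 1 and 2, and to 30146559 and 33074965 in resistant replicates 1 and 2. Between 21067 and 21737 of the 57773 listed genes had a count above 0 in each library, and 16090 genes had enough counts to be tested. A count of 0 allows a level of up to 3 counts, which corresponded to between 0.0801 and 0.104 CPM, the read count normalised to library size. Across tested genes, which are not independent replicates, Pearson's r of log2 CPM was 0.985 between the untreated libraries, 0.98 between the resistant ones and 0.91 to 0.931 between the groups. The first principal component held 80.2% of the variance and separated the groups. Intervals and floors cover counting error only, and p-values measure the spread between these libraries, since the labels do not say that the replicates were cultured apart.

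The comparison of resistant with untreated cells asks which genes differ in cells selected for growth in this drug. In the resistant libraries most genes of the ERK output list, transcribed when ERK is active, were lower, and so were most G1/S and E2F targets, which copy DNA, whereas most genes of the cholesterol synthesis and interferon response lists were higher. These lists were called with a preset correlation between genes and not with an estimated one (adjusted p = 0.703), which had little power with 4 libraries. ETV4, a transcription factor induced by ERK, fell from 35.5 ± 3.25 CPM to 2.31 ± 0.295 CPM (SD, n = 2), and CCND1, the cyclin D1 that drives entry into the cell cycle, fell from 169 ± 26.4 CPM to 35.8 ± 3.91 CPM. EGFR, a receptor tyrosine kinase upstream of RAS, rose from 227 ± 31.6 CPM to 519.7 ± 8.94 CPM. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5463 of the 16090 tested genes (34%) were called at an adjusted p below 0.05, of which 2669 were higher and 2794 lower in resistant cells. Among them 2785 differed at least 2-fold, 1571 higher and 1214 lower, and 2295 of these (82.4%) differed at least 2-fold in the same direction in each resistant library. In 11406 tested genes (70.9%) the values of the 2 groups did not overlap, where chance gives 33.3%. Without untreated replicate 1 the number of calls was 2832, with 1510 higher and 1322 lower. Chromosomes differed as well. The median log2 fold change of protein-coding genes was 0.46 on chromosome 22 (which holds SREBF2, HMOX1 and XBP1) and 0.42 on chromosome 11 (CCND1). It was 0.22 on chromosome 7 (EGFR, MET, ETV1) and −0.41 on chromosome 5 (SPRY4). On chromosome 20 (NTSR1) it was −0.06 in the first and −0.63 in the second part of the gene order. Values of CCND1, FGFR1, ERBB2, FGF2, SHC1, TNC, LOXL2, VIM, ZEB1, SLC16A3, GAPDH, ANGPTL4, ANLN, IRF1, CTSD, EPHA4, PHLDA1, ENC1, MEST and MT-ND4 are uncertain to the extent that they share reads with an overlapping gene, since the strand setting is not known.

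**Figure D1:**
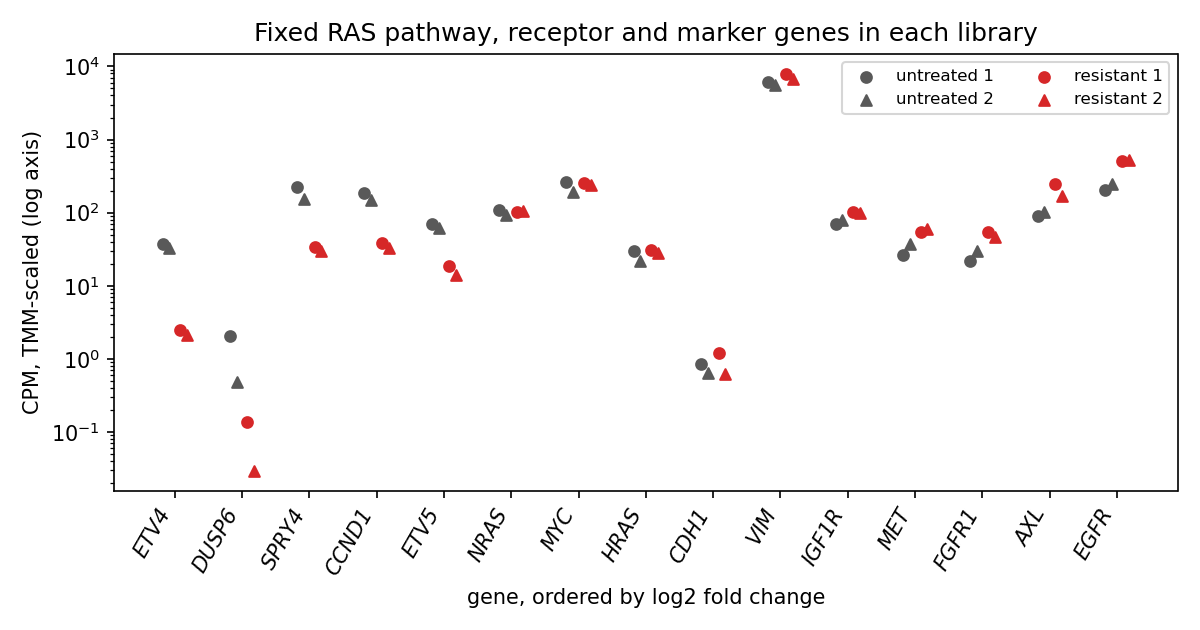
Each point is the level in 1 library of a gene fixed in advance, in CPM on a log axis, for the untreated and the resistant libraries, with genes ordered by log2 fold change. ETV4 lies lowest relative to untreated cells (log2 fold change −3.94) and EGFR highest (1.19).

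The ERK output list, genes whose transcription follows ERK activity, moved down. Of its 20 tested members 13 fell, 2 rose and 5 did not pass (13 and 2 adjusted over the list alone). The median log2 fold change was −1.24. Camera, which compares a list with all other genes, called it at an adjusted p = 3.01e-04 (adjusted p = 0.703 with an estimated correlation). ETV1, an ETS transcription factor (ENSG00000006468, chromosome 7), had 2806 counts in untreated and 3 in resistant libraries, a ratio of 789 with a 95% counting interval of 269.8 to 3830. Its log2 fold change was −9.52, and −10.14 without resistant replicate 1. SPRY4, a feedback inhibitor of the pathway, fell from 188 ± 50.6 CPM to 31.5 ± 2.86 CPM (log2 fold change −2.58, SE 0.21, adjusted p = 2.58e-05). ETV4 had a log2 fold change of −3.94 (SE 0.24, adjusted p = 2.55e-06) and is uncertain, since it overlaps DHX8, an expressed gene on the opposite strand. ETV5, a related factor without such an overlap, fell from 66.0 ± 6.26 CPM to 16.4 ± 3.03 CPM (log2 fold change −2.01, SE 0.19, adjusted p = 5.95e-05). CCND1 fell by 2.24 in log2 (SE 0.18, adjusted p = 1.98e-05). DUSP6, a phosphatase that inactivates ERK, was low in both groups, at 1.27 ± 1.12 CPM in untreated and 0.0838 ± 0.0767 CPM in resistant libraries (log2 fold change −3.91, SE 0.94, adjusted p = 0.0112). Its call ended without untreated replicate 1, at a log2 fold change of −2.49 and an adjusted p = 0.175. Its log2 fold change was −4.62 without untreated replicate 2, −5.26 without resistant replicate 1 and −3.17 without resistant replicate 2. The 2 risers were DUSP5, another ERK phosphatase (log2 fold change 2.05, SE 0.34, adjusted p = 0.00155), and EPHA4, an ephrin receptor (0.58, SE 0.16, adjusted p = 0.0197), both named after their values were seen. EPHA4 was not called without untreated replicate 1 or resistant replicate 1 (adjusted p up to 0.138). PHLDA1 (0.15, adjusted p = 0.655) and MYC (0.14, SE 0.18, adjusted p = 0.601) did not pass.

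The RAS and RAF-MEK-ERK components, which carry the signal from receptors to ERK, were not called as a list (camera adjusted p = 0.254), with 5 of 29 members higher, 1 lower and 23 not passing (5 and 1 adjusted over the list alone). RRAS2, a RAS-related GTPase, rose from 44.8 ± 10.5 CPM to 325.5 ± 15.6 CPM (log2 fold change 2.86, SE 0.20, adjusted p = 7.61e-06). SHC1, an adaptor between receptors and RAS, rose from 508.2 ± 77.1 CPM to 1036 ± 147 CPM. MRAS and RRAS, further RAS-related GTPases, had log2 fold changes of 1.65 (SE 0.28) and 1.15 (SE 0.21). The member that fell was GRB2, an adaptor that brings the exchange factor SOS to receptors (−0.66, SE 0.16, adjusted p = 0.00882), chosen after its value was seen and not called without untreated replicate 1 (adjusted p = 0.0724). HRAS (0.20, adjusted p = 0.480) and NRAS (0.06, adjusted p = 0.787) did not pass.

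Among receptor tyrosine kinases 7 of 24 tested members rose, 2 fell and 15 did not pass (9 and 2 adjusted over the list alone), and the list was not called (camera adjusted p = 0.180). EGFR had a log2 fold change of 1.19 (SE 0.17, adjusted p = 7.03e-04). AXL, a receptor for GAS6, rose from 96.8 ± 8.75 CPM to 207.6 ± 54.5 CPM (1.10, SE 0.20, adjusted p = 0.00247). FGFR1, a fibroblast growth factor receptor, rose by 0.96 (SE 0.20, adjusted p = 0.00428). DDR1, a collagen receptor, rose by 1.01 (SE 0.16, adjusted p = 0.00124). MET, the receptor for hepatocyte growth factor, rose by 0.85 (SE 0.19, adjusted p = 0.00738), a call that ended without untreated replicate 1 (adjusted p = 0.0566). EPHB2, an ephrin receptor, fell from 28.3 ± 1.80 CPM to 5.78 ± 1.29 CPM (−2.29, SE 0.24, adjusted p = 1.03e-04). IGF1R, the receptor for insulin-like growth factor 1, had a log2 fold change of 0.43 (SE 0.15, adjusted p = 0.0511). ERBB2 had one of −0.03 (SE 0.16, adjusted p = 0.908), which was above 0 with a stricter filter or without resistant replicate 2. Of the growth factor ligands 9 of 20 rose, 3 fell and 8 did not pass (9 and 4 adjusted over the list alone; camera adjusted p = 0.115). The ligands passed as a list without untreated replicate 1 or with a stricter filter (adjusted p down to 0.0219). FGF2, a ligand of FGFR1, rose from 31.9 ± 6.98 CPM to 184 ± 2.09 CPM (2.53, SE 0.19, adjusted p = 1.19e-05). BTC, a ligand of EGFR, rose from 15.1 ± 0.239 CPM to 42.5 ± 3.64 CPM (adjusted p = 2.90e-04). The PI3K-AKT-mTOR components, a growth pathway beside RAF-MEK-ERK, had 7 risers, 6 fallers and 12 not passing among 25 (7 and 6 adjusted over the list alone; camera adjusted p = 0.707). DDIT4, an inhibitor of mTOR complex 1, rose from 92.3 ± 4.88 CPM to 377.4 ± 122 CPM. AKT1 did not pass (−0.33, adjusted p = 0.153).

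The genes that follow were among the 10 largest rises and the 10 largest falls of called genes with at least 10 CPM, of which not all are given here. EDNRB, an endothelin receptor (ENSG00000136160, chromosome 13), had 0 counts in the untreated libraries and 1049 in the resistant ones, at least 414-fold higher against 3 counts over the group. TNC, the matrix protein tenascin C (ENSG00000041982, chromosome 9), rose from 0.984 ± 0.447 CPM to 2241 ± 853.9 CPM (log2 fold change 11.15, SE 0.47, adjusted p = 6.90e-06). DIO2, an enzyme that activates thyroid hormone, had 3 counts in untreated and 3194 in resistant libraries, a ratio of 1262 (95% counting interval 431 to 6120). TGFB2, a ligand of the TGF-beta family, rose from 0.108 ± 0.00103 CPM to 44.3 ± 7.86 CPM (8.64, SE 0.34, adjusted p = 1.58e-07). ALPK2, an alpha-type kinase, rose to 179 ± 59.6 CPM (8.98, SE 0.38). NTS, the peptide neurotensin, rose to 824 ± 35.6 CPM (8.26, SE 0.36, and 8.91 without untreated replicate 1). NTSR1, the receptor for neurotensin, fell from 73.5 ± 16.4 CPM to 0.301 ± 0.258 CPM (−7.97, SE 0.42). Its log2 fold change was −9.22 without resistant replicate 1 and −7.24 without resistant replicate 2. TMEM158, a transmembrane protein, fell from 32.2 ± 7.38 CPM to 0.698 ± 0.233 CPM (−5.54, SE 0.33, adjusted p = 2.32e-06). CTSC, the protease cathepsin C, fell from 122.7 ± 81.2 CPM to 0.234 ± 0.0874 CPM (−8.98, SE 0.84, adjusted p = 0.00284). It was not called without resistant replicate 2 (adjusted p = 0.193), and its log2 fold change was −8.05 without untreated replicate 1. KLRC2, with a ratio of 2638 from 1 untreated count (interval 473 to 104200), is uncertain because it has near-identical paralogs. The log2 fold change of KLRC2 was 11.02, but 13.20 without untreated replicate 2 and 10.21 without untreated replicate 1.

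**Figure D2:**
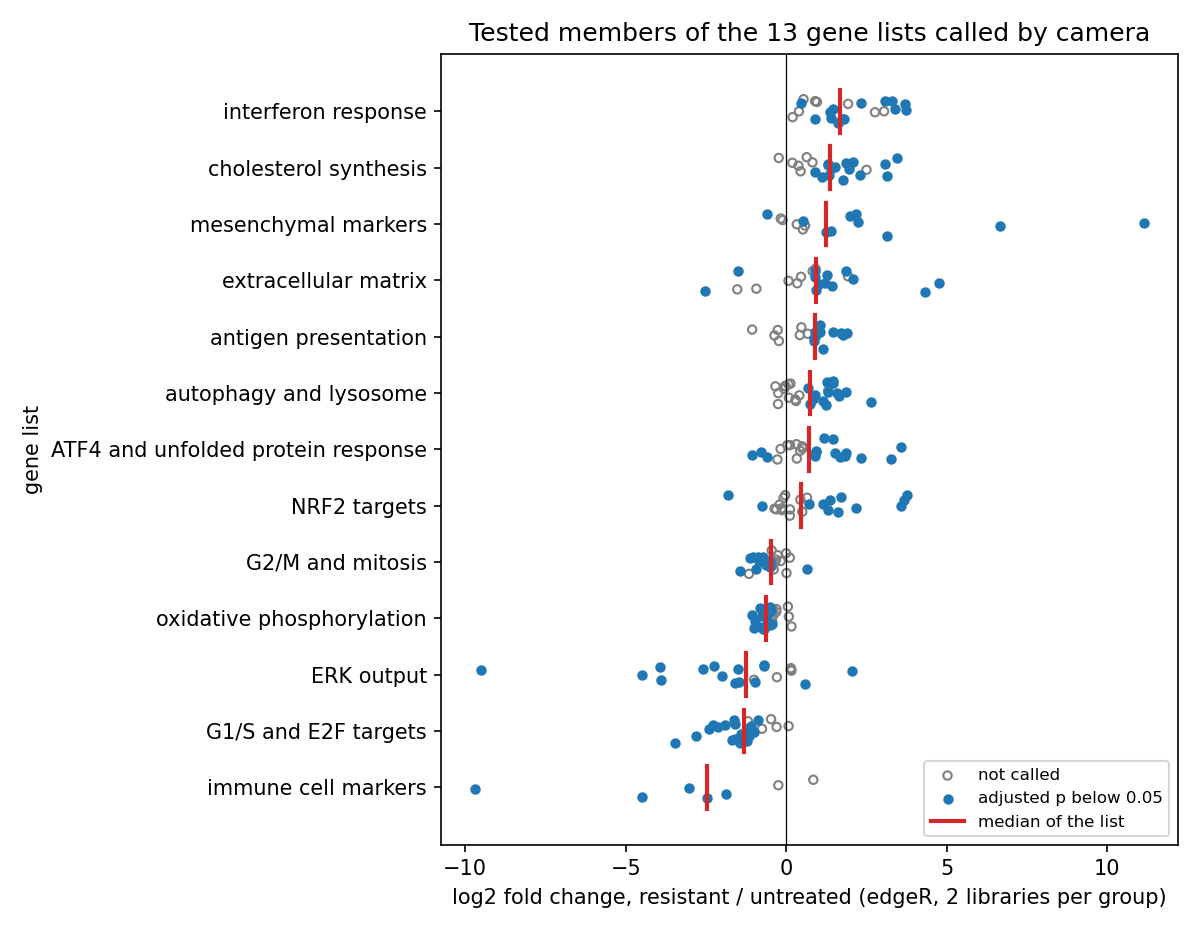
Each point is the log2 fold change (resistant over untreated) of a tested member of the 13 called lists, filled where its adjusted p lies below 0.05 and open where not, and each bar is the list's median. Medians range from −2.48 for immune cell markers to 1.68 for the interferon response.

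Mesenchymal markers, genes of motile matrix-producing cells, were higher: 9 of 15 tested members rose, 1 fell and 5 did not pass (10 and 1 adjusted over the list alone). The list was called at a camera adjusted p = 0.00104 (adjusted p = 0.703 with an estimated correlation). SPARC, a matrix glycoprotein, rose from 0.431 ± 0.118 CPM to 44.1 ± 5.17 CPM (log2 fold change 6.67, SE 0.29, adjusted p = 3.48e-07). LOXL2, an enzyme that crosslinks collagen, rose from 565.9 ± 12.1 CPM to 1323 ± 216.5 CPM (adjusted p = 7.42e-04). The member that fell was S100A4, a calcium-binding protein (−0.61, SE 0.17, adjusted p = 0.0175), chosen after its value was seen and not called without untreated replicate 1 or resistant replicate 1 (adjusted p up to 0.179). VIM, the intermediate filament vimentin, did not pass (0.33, SE 0.17, adjusted p = 0.160), nor did ZEB1 (−0.11, adjusted p = 0.654). Of the extracellular matrix genes 11 of 21 rose, 2 fell and 8 did not pass (12 and 2 adjusted over the list alone). The list's camera adjusted p = 0.00575 became adjusted p = 0.703 with an estimated correlation and 0.0838 without resistant replicate 1. COL1A2, a chain of type I collagen, rose from 243.4 ± 39.9 CPM to 4847 ± 96.3 CPM (4.31, SE 0.20, adjusted p = 5.20e-07). LAMC1, a laminin chain, rose from 112.5 ± 13.2 CPM to 305.4 ± 4.87 CPM (1.44, SE 0.17, adjusted p = 2.07e-04). COL6A3 (−2.53, SE 0.33) and COL13A1 (adjusted p = 0.0286), further collagen chains chosen after their values were seen, fell. COL13A1 was not called without untreated replicate 2 or resistant replicate 2 (adjusted p up to 0.125).

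Integrins and focal adhesion genes, which attach cells to matrix, were not called (camera adjusted p = 0.536), with 6 of 23 higher, 4 lower and 13 not passing (7 and 4 adjusted over the list alone). Their median (0.20) and mean (−0.03) differed in sign. CAV2, a caveolin, rose by 1.44 (SE 0.19, adjusted p = 3.85e-04), and ITGAV, an integrin chain, by 1.01 (SE 0.19, adjusted p = 0.00262). Epithelial markers moved both ways, with 3 of 18 higher, 4 lower and 11 not passing (3 and 4 adjusted over the list alone; camera adjusted p = 0.536). KRT8, an epithelial keratin, fell from 2583 ± 717.9 CPM to 1103 ± 200.3 CPM (−1.23, SE 0.22, adjusted p = 0.00268), with some uncertainty because it overlaps KRT18. CDH1, the adhesion protein E-cadherin, was low in both groups, at 0.754 ± 0.159 CPM in untreated and 0.915 ± 0.414 CPM in resistant libraries. It did not pass (0.27, adjusted p = 0.737), and its log2 fold change was below 0 without resistant replicate 1.

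Of 27 tested G1/S and E2F targets, which copy DNA, 22 fell, 0 rose and 5 did not pass (24 and 0 adjusted over the list alone). Their median log2 fold change was −1.30, with a camera adjusted p = 4.39e-08 (adjusted p = 0.703 with an estimated correlation). CDC6, which licenses replication origins, fell from 77.8 ± 24.2 CPM to 17.9 ± 3.25 CPM (−2.12, SE 0.24, adjusted p = 2.93e-04). MCM6, a subunit of the replicative helicase, fell from 200.4 ± 31.0 CPM to 85.7 ± 11.9 CPM (−1.22, SE 0.18, adjusted p = 8.34e-04). RRM1, a subunit of ribonucleotide reductase, did not pass (−0.47, adjusted p = 0.0726). Of the G2/M and mitosis genes 11 of 26 fell, 1 rose and 14 did not pass (12 and 1 adjusted over the list alone). Camera gave an adjusted p = 0.00104 (adjusted p = 0.703 with an estimated correlation). KIF11, a motor of the spindle, fell by 1.12 (SE 0.20, adjusted p = 0.00270) and PLK1, a mitotic kinase, by 0.93 (SE 0.18, adjusted p = 0.00300). TOP2A, a topoisomerase, did not pass (−0.36, adjusted p = 0.105). The riser was ANLN, a scaffold of cell division (0.65, SE 0.19, adjusted p = 0.0231), chosen after its value was seen and not called without untreated replicate 2 or resistant replicate 2 (adjusted p up to 0.171). Among cell cycle inhibitors and cyclins D 6 of 13 rose, 3 fell and 4 did not pass (6 and 4 adjusted over the list alone; camera adjusted p = 0.720). Fry gave their direction as down where camera, median and mean were up. CDKN2D, an inhibitor of CDK4 and CDK6, rose by 1.38 (SE 0.25, adjusted p = 0.00224). CCND3, a D-type cyclin, fell by 0.96 (SE 0.19, adjusted p = 0.00390), and RBL1, a relative of the retinoblastoma protein, fell by 1.59 (SE 0.22). CDKN2A had 0 counts in all 4 libraries.

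Targets of the YAP/TEAD transcription factors were not called as a list (camera adjusted p = 0.0610), with 7 of 20 higher, 2 lower and 11 not passing (8 and 3 adjusted over the list alone). The list passed without untreated replicate 1, without resistant replicate 2 or with a stricter filter (adjusted p down to 0.0366). GADD45A, a stress-induced growth regulator, rose from 16.3 ± 1.05 CPM to 222 ± 84.9 CPM (3.77, SE 0.27, adjusted p = 3.84e-05). LATS2, a kinase that restrains YAP, rose from 43.5 ± 4.92 CPM to 150 ± 22.1 CPM. NT5E, an enzyme that makes adenosine, fell from 325.8 ± 52.7 CPM to 25.8 ± 0.798 CPM (−3.66, SE 0.19, adjusted p = 9.47e-07). Of the TGF-beta targets 6 of 18 rose, 3 fell and 9 did not pass (6 and 3 adjusted over the list alone; camera adjusted p = 0.219). BAMBI, a decoy receptor of the pathway, rose from 4.25 ± 1.26 CPM to 48.6 ± 0.426 CPM (3.51, SE 0.24). TGFBR3, a co-receptor, rose from 57.1 ± 6.58 CPM to 314.6 ± 21.7 CPM (2.46, SE 0.17). In the WNT pathway and its targets 4 of 20 rose, 5 fell and 11 did not pass (4 and 5 adjusted over the list alone; camera adjusted p = 0.254, and 0.0428 without resistant replicate 1). LGR4, a receptor that strengthens WNT signals, rose by 1.76 (SE 0.25, adjusted p = 6.76e-04). TCF7, a transcription factor of the pathway, fell from 517.5 ± 19.2 CPM (−5.01, SE 0.19), and is uncertain because it overlaps SKP1. In the NOTCH pathway 4 of 16 rose, 3 fell and 9 did not pass (4 and 4 adjusted over the list alone; camera adjusted p = 0.611). HES4, a target of NOTCH, rose by 1.63 (SE 0.23, adjusted p = 6.87e-04). NRARP, a feedback inhibitor, fell by 0.96 (SE 0.20, adjusted p = 0.00449).

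For cholesterol synthesis 14 of 22 tested genes rose, 0 fell and 8 did not pass (15 and 0 adjusted over the list alone). Their median log2 fold change was 1.38, with a camera adjusted p = 2.76e-05 (adjusted p = 0.703 with an estimated correlation). SREBF2, the transcription factor that controls the pathway, rose from 130 ± 23.6 CPM to 441.3 ± 71.8 CPM (1.77, SE 0.20, adjusted p = 1.56e-04). For fatty acid synthesis and desaturation 8 of 17 rose, 2 fell and 7 did not pass (8 and 3 adjusted over the list alone; camera adjusted p = 0.120, and 0.0410 without untreated replicate 1). ME1, which supplies NADPH, rose by 1.35 (SE 0.16, adjusted p = 2.09e-04). ELOVL6, a fatty acid elongase, fell by 1.96 (SE 0.32, adjusted p = 0.00148). Of the oxidative phosphorylation genes, subunits of the mitochondrial respiratory chain, 19 of 27 fell, 0 rose and 8 did not pass (22 and 0 adjusted over the list alone). Their median was −0.62, with a camera adjusted p = 2.76e-05 (adjusted p = 0.703 with an estimated correlation). UQCRC2, a subunit of complex III, fell from 254.4 ± 6.74 CPM to 121.1 ± 5.61 CPM (−1.07, SE 0.16, adjusted p = 8.34e-04). COX7C, a subunit of complex IV, did not pass (−0.44, adjusted p = 0.0523). In the same libraries MALAT1, a nuclear RNA read as a sign of RNA composition, was higher by 2.24 (SE 0.17). Glycolysis genes were not called (camera adjusted p = 0.238), with 2 of 22 higher, 5 lower and 15 not passing (2 and 5 adjusted over the list alone). SLC16A3, a lactate exporter, fell by 0.91 (SE 0.16, adjusted p = 0.00225), and GAPDH did not pass (−0.08, adjusted p = 0.737). In the hypoxia response 6 of 17 rose, 2 fell and 9 did not pass (7 and 2 adjusted over the list alone; camera adjusted p = 0.162). ANGPTL4, a secreted lipase inhibitor, rose by 1.62 (SE 0.20, adjusted p = 3.52e-04).

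Of the autophagy and lysosome genes 14 of 27 rose, 0 fell and 13 did not pass (15 and 0 adjusted over the list alone). Camera gave an adjusted p = 6.43e-04 (adjusted p = 0.703 with an estimated correlation). TFE3, a transcription factor of lysosomal genes, rose from 53.3 ± 9.56 CPM to 192 ± 24.2 CPM (1.85, SE 0.19, adjusted p = 8.10e-05). TFE3 is 1 of the 25 neighbouring protein-coding genes in the window, on chromosome X, with the largest median of all windows. Of these 25 genes 19 rose and 0 fell, beside 2669 higher and 2794 lower among the 16090 tested genes. The window was picked for its median, so a high number of risers follows from that choice. GABARAPL1, an autophagosome protein, rose from 16.2 ± 5.06 CPM to 102.0 ± 19.2 CPM (2.65, SE 0.24). CTSD, a lysosomal protease, did not pass (−0.06, adjusted p = 0.789). Of the NRF2 targets, which answer oxidative stress, 10 of 24 rose, 2 fell and 12 did not pass (11 and 2 adjusted over the list alone). The camera value was adjusted p = 0.0217, adjusted p = 0.703 with an estimated correlation and adjusted p = 0.107 without untreated replicate 2. AKR1B1, an aldose reductase, rose from 132 ± 4.12 CPM to 1808 ± 593.2 CPM (3.77, SE 0.24, adjusted p = 6.90e-06). HMOX1, which degrades heme, rose to 116.9 ± 1.42 CPM (2.16, SE 0.16). The members that fell, chosen after their values were seen, were GCLM (−1.81, SE 0.18) and GSR (−0.75, SE 0.15), enzymes of glutathione supply. Of the genes of ATF4 and the unfolded protein response 12 of 24 rose, 3 fell and 9 did not pass (13 and 3 adjusted over the list alone). The camera value was adjusted p = 0.0149, adjusted p = 0.703 with an estimated correlation and adjusted p = 0.165 without untreated replicate 2. XBP1, a transcription factor of the response, rose from 71.1 ± 9.13 CPM to 204 ± 69.9 CPM (1.52, SE 0.24, adjusted p = 0.00155). SHMT2 (−0.79) and PHGDH (−0.61), enzymes of serine and glycine synthesis, and SDF2L1 (−1.07), a protein of the endoplasmic reticulum, fell and were chosen after their values were seen. PHGDH was not called without untreated replicate 2 (adjusted p = 0.131) nor SDF2L1 without untreated replicate 1 (adjusted p = 0.101). Drug transporters and xenobiotic enzymes were not called (camera adjusted p = 0.3995), with 3 of 19 higher, 5 lower and 11 not passing (4 and 5 adjusted over the list alone). SULT1A1, a sulfotransferase, rose by 2.34 (SE 0.30, adjusted p = 5.88e-04). The efflux pump ABCB1 had 5, 5, 4 and 1 counts in untreated replicates 1 and 2 and resistant replicates 1 and 2, too few to test.

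Interferon response genes were higher, with 14 of 22 tested members rising, 0 falling and 8 not passing (18 and 0 adjusted over the list alone). Their median log2 fold change was 1.68, with a camera adjusted p = 1.90e-06 (adjusted p = 0.703 with an estimated correlation). ISG15, a ubiquitin-like protein, rose from 26.7 ± 8.85 CPM to 93.6 ± 18.9 CPM (1.81, SE 0.25, adjusted p = 0.00107). IRF1, a transcription factor of the response, rose from 14.7 ± 2.92 CPM to 38.5 ± 6.62 CPM (1.39, SE 0.22, adjusted p = 0.00116). STAT2 did not pass (0.54, SE 0.20, adjusted p = 0.0585). Of the antigen presentation genes 12 of 19 rose, 0 fell and 7 did not pass (13 and 0 adjusted over the list alone). Camera gave an adjusted p = 0.00234 (adjusted p = 0.703 with an estimated correlation). B2M, the light chain of class I molecules, rose from 212.2 ± 9.87 CPM to 466.8 ± 30.1 CPM (1.14, SE 0.16, adjusted p = 6.91e-04). TAPBP, which loads peptides, rose by 1.47 (SE 0.19, adjusted p = 3.69e-04). NF-kB targets and inflammatory cytokines moved both ways, with 3 of 17 higher, 4 lower and 10 not passing (4 and 5 adjusted over the list alone; camera adjusted p = 0.707). CXCL1 fell from 34.7 ± 9.92 CPM to 7.67 ± 0.209 CPM (−2.18, SE 0.24, adjusted p = 1.56e-04). CXCL8 fell from 31.6 ± 14.0 CPM to 4.08 ± 1.16 CPM (−2.96, SE 0.35), and both are chemokines that attract neutrophils. CCL2, a chemokine of monocytes, had 1 count in untreated and 427 in resistant libraries, a ratio of 505.9 (95% counting interval 90.3 to 20030). The log2 fold change of CCL2 was 8.62, but 10.80 without untreated replicate 2, which held that count, and 7.80 without untreated replicate 1.

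Lists of apoptosis and lineage genes did not pass. Of the BCL2 family and apoptosis genes 2 of 23 rose, 3 fell and 18 did not pass (1 and 3 adjusted over the list alone; camera adjusted p = 0.707). BCL2, which blocks apoptosis, fell from 6.39 ± 0.689 CPM to 0.673 ± 0.220 CPM (−3.23, SE 0.41, adjusted p = 3.67e-04). BIRC2, an inhibitor of apoptosis, rose by 0.96 (SE 0.18, adjusted p = 0.00304). MCL1 did not pass (0.28, adjusted p = 0.264). Among stemness and pancreatic lineage factors 1 of 12 rose, 1 fell and 10 did not pass (1 and 1 adjusted over the list alone; camera adjusted p = 0.707). TP63, a transcription factor of basal epithelium, rose from 105.9 ± 2.37 CPM to 210.4 ± 48.3 CPM (0.99, SE 0.19, adjusted p = 0.00287). Of 7 neuroendocrine markers 1 fell, 0 rose and 6 did not pass (1 and 0 adjusted over the list alone; camera adjusted p = 0.426).

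Of 7 tested immune cell markers 5 fell, 0 rose and 2 did not pass (5 and 0 adjusted over the list alone). Their median log2 fold change was −2.48, also with genes at 0 set to their bound. Camera gave an adjusted p = 0.00104 (adjusted p = 0.703 with an estimated correlation). CORO1A, an actin-binding protein abundant in leukocytes, fell from 17.2 ± 3.01 CPM to 2.10 ± 0.159 CPM (−3.03, SE 0.29, adjusted p = 5.43e-05). LAPTM5, a lysosomal protein of blood cells, had 225 counts in untreated and 0 in resistant libraries, at least 63.3-fold lower. PTPRC, the pan-leukocyte marker CD45, had 2, 5, 3 and 2 counts in the 4 libraries. Of 6 endothelial and erythroid markers 2 fell, 0 rose and 4 did not pass (2 and 0 adjusted over the list alone; camera adjusted p = 0.238, and 0.0303 without resistant replicate 1). Of 25 stress and RNA quality genes 4 rose, 8 fell and 13 did not pass (4 and 11 adjusted over the list alone; camera adjusted p = 0.180). MALAT1, a nuclear RNA, rose from 152.2 ± 3.66 CPM to 718.9 ± 4.06 CPM (2.24, SE 0.17, adjusted p = 1.08e-05). NEAT1, a nuclear RNA of paraspeckles, rose from 316.5 ± 66.6 CPM to 2232 ± 708.9 CPM (2.82, SE 0.26, adjusted p = 9.39e-05). MT-CYB, encoded by the mitochondrial genome, fell from 2087 ± 171.5 CPM to 1031 ± 114.4 CPM (−1.02, SE 0.17, adjusted p = 0.00170). MT-ND4 did not pass (0.08, adjusted p = 0.764). Of the 13 protein-coding genes of the mitochondrial genome, counted after the result had been seen, 7 fell and 0 rose. Of 26 cytosolic ribosomal protein genes 1 rose, 2 fell and 23 did not pass, and 0 rose and 0 fell adjusted over the list alone (camera adjusted p = 0.536). Mitochondrial genes held 5.08% and 6.02% of the counts in untreated and 5.21% and 4.71% in resistant replicates 1 and 2.

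The 2 resistant populations of the design text can be set side by side without a test, since each was sequenced as 1 library. ENC1, an actin-binding protein, stood at 45.1 CPM in resistant replicate 1 and at 213.9 CPM in replicate 2, and at 161.7 and 115.9 CPM in the untreated libraries. HMGCS1, an enzyme of cholesterol synthesis, stood at 681.4 and 180.1 CPM in resistant replicates 1 and 2, against 44.4 and 34.3 CPM in the untreated libraries. MAP2, a microtubule-associated protein, stood at 68.8 CPM in resistant replicate 1 and 17.4 CPM in replicate 2, against 0.569 and 0.454 CPM in the untreated libraries. TLE1, a transcriptional co-repressor, stood at 32.8 and 6.96 CPM, against 46.7 and 44.8 CPM untreated. MEST, an imprinted gene, and SHC2, an adaptor, were also higher in replicate 1, with log2 ratios of 3.52 and 2.04. SAMD9L, an interferon-induced gene, was lower in replicate 1 (2.62 CPM) than in replicate 2 (11.3 CPM), against 0.406 and 0.454 CPM untreated. JAG1, a NOTCH ligand, stood at 9.70 and 28.6 CPM, against 193.4 and 191.7 CPM untreated, so it was far lower in both resistant libraries. COL17A1, a collagen of epithelial anchorage, stood at 28.1 and 74.4 CPM, against 127.8 and 101.9 CPM untreated. Differences of at least 2-fold in CPM were found in 1109 tested genes between the resistant libraries and in 1113 between the untreated ones. Among genes of at least 10 CPM the numbers were 165 of 9955 between the resistant libraries, 114 higher and 51 lower in replicate 1, and 87 of 9939 between the untreated ones.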

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

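Tests with edgeR's newer quasi-likelihood form were chosen only after the result had been seen; the other settings were planned. With the libraries left out in turn, between 2832 (without untreated replicate 1) and 5041 (without resistant replicate 2) genes were called, beside 5463 with all libraries, of which 1510 to 2548 were higher and 1322 to 2493 lower. In such fits the lone library of a group is assumed to vary like the other group. Without untreated replicate 1, 2749 of the 2832 calls were also called with all libraries, all in the same direction, and the cause of the lower number was not tested. At an adjusted p below 0.01 instead of 0.05, 2832 genes were called, 1444 higher and 1388 lower, by construction fewer. Other scalings, filters and tools gave 5201 (stricter filter) to 6235 calls (no filter), with the share of higher calls between 49.2% and 51% (48.9% in the comparison itself), and the median log2 fold change of all genes between −0.013 and 0.013 over the 3 scalings. The replicate block gave 5275 calls, 5100 of them shared. Deviations from the group means correlated at −0.06 between libraries of the same number, so the numbers give no sign of pairs. The block left the same 13 lists called. With an estimated correlation between genes camera called 0 of the 36 lists (smallest adjusted p = 0.703), where the preset one gave 13. Fry called 2, NRF2 targets and immune cell markers (adjusted p = 0.0463 for both). For these 2 the estimated correlation (−0.0391 and −0.116) was below the preset 0.01. Yet camera's unadjusted p rose from 0.00784 to 0.0983 and from 2.61e-04 to 0.064, so a higher correlation cannot account for their loss. For the other called lists the estimate lay above the preset 0.01, from 0.177 (antigen presentation) to 0.82 (cholesterol synthesis). Their camera p-values with the preset correlation may therefore be too small. The estimated form takes its degrees of freedom from the 4 libraries rather than from the genes. It had little power here, and its adjusted p = 0.703 cannot decide whether a list moved. With a library left out, 11 to 16 lists were called. Of 273 named genes, 241 stayed on the same side of the threshold without untreated replicate 1 and 31 lost their call, and with DESeq2 260 stayed and 2 lost it. ENC1 was the only named gene whose sign reversed together with a call; some genes that were not called also changed sign. It had a log2 fold change of −0.10 (adjusted p = 0.950) with all libraries, 0.64 (adjusted p = 0.0382) without resistant replicate 1 and −1.62 without resistant replicate 2, and its level differed between the resistant libraries. Between the resistant libraries 575 genes instead of 1109 were at least 2-fold apart with a stricter filter, which tests 13923 genes in place of 16090 (600 instead of 1113 between the untreated ones). Depth limits what can be said below about 0.104 CPM, the level that 3 counts stand for in the shallowest library.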

Other observations

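The edgeR test of single genes, apart from its quasi-likelihood form, and camera on the fixed lists were planned. The correction of the ERK output list for GC content, transcript length and expression level was written down before its result was seen. All other tests given here were chosen only after the result had been seen. The genes in the next paragraph and those named on chromosome X were also chosen after their values were seen.

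Genes outside the fixed lists changed at high levels. ATP1B1, a subunit of the sodium pump, rose from 51.0 ± 6.68 CPM to 1313 ± 211.2 CPM (log2 fold change 4.69, SE 0.21, edgeR adjusted p = 5.20e-07). SLC39A8, a transporter of zinc and manganese, rose from 19.6 ± 6.81 CPM to 713 ± 54.0 CPM (5.19, SE 0.27, adjusted p = 1.94e-06). ELF5, an epithelial ETS transcription factor, rose from 1.81 ± 1.03 CPM to 163.9 ± 17.6 CPM (6.50, SE 0.36, adjusted p = 2.15e-05, and 7.23 without untreated replicate 2). CALB2, the calcium-binding protein calretinin, fell from 250.7 ± 20.2 CPM to 8.03 ± 3.57 CPM (−4.97, SE 0.31, adjusted p = 2.15e-05). TGM2, a transglutaminase that crosslinks proteins, fell from 618.4 ± 134.9 CPM to 74.5 ± 27.8 CPM (−3.05, SE 0.29), and RGS5, which restrains G protein signals, fell from 793.8 ± 282.6 CPM to 110.6 ± 14.7 CPM (−2.84, SE 0.26). ATP1B1, SLC39A8, TGM2 and RGS5 overlap other expressed genes and are uncertain to that extent. NOP58, a nucleolar protein, fell from 117.5 ± 34.9 CPM to 35.3 ± 6.06 CPM (−1.73, SE 0.22, adjusted p = 5.96e-04), NOP56, another one, from 265.9 ± 92.8 CPM to 89.4 ± 7.95 CPM (−1.57, SE 0.23, adjusted p = 0.00125), and PRMT5, an arginine methyltransferase, from 162 ± 24.7 CPM to 56.9 ± 4.13 CPM (−1.51, SE 0.17, adjusted p = 1.85e-04). These are single genes, and no list of them was tested.

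Of 20 tested ERK output genes 13 fell in the resistant libraries, 2 rose and 5 did not pass, with a median log2 fold change of −1.24 (camera adjusted p = 3.01e-04, and 0.703 with an estimated correlation). After the trend on GC content, transcript length and expression level was removed, which explained 1.28% of the deviance, the median was −1.31, outside the range of −0.412 to 0.327 that holds the central 95% of 10000 random lists matched on expression, so that trend alone cannot account for it. The resistant cells' long growth in AMG510, and the drug itself if it was present at harvest, remain open and untested explanations.

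Chromosomes shifted between the groups in whole or in part: 8 of 23 chromosomes had a median that stood out when blocks of 25 neighbouring genes were shuffled 2000 times in a permutation test (chromosomes 5, 7, 11, 20 and 22 at p = 5e-04, the smallest that these shuffles can give, adjusted p = 0.0023), 5 higher and 3 lower, against 0 between the untreated libraries. After the same correction for GC content, length and level 8 of the 8 stayed shifted, so that bias alone cannot account for them. A culture with an intact CDKN2A to MTAP region in place of the resistant cells is argued against by the level of CDKN2A, CDKN2B and MTAP, 0.032 CPM together in the resistant libraries (2 counts) and 0 counts in the untreated ones. A candidate explanation is a change in chromosome copy number. In 5 of the 8 both parts of the gene order, the first and the second, had moved the same way. They did so by over 0.1 in both resistant libraries. The 8 were picked by their whole median, which favours chromosomes whose parts agree, so this count cannot decide for a copy number change. Among chromosomes not picked, the parts stood at −0.463 and 0.17 on chromosome 16 and at −0.191 and −0.174 on chromosome 8. On chromosome 3 the parts had medians of opposite sign (−0.14 and 0.373). On chromosomes X (0.359 and −0.0834) and 20 (−0.056 and −0.626) only 1 part moved by over 0.1. The other part of X lay near the median of chromosome 1 (−0.0823), which was not shifted. A copy number change of part of a chromosome would allow such values. No DNA data were used here, and regulation over long stretches, such as the windows centred from WDR13 to CCDC22 on chromosome X (largest median 1.26; HDAC6 1.42, PIM2 1.63, KCND1 3.53), would allow these values too and stays open beside it, as does what long growth in the drug did to these populations.

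MALAT1 and NEAT1, RNAs kept in the nucleus, rose, while 19 of 27 oxidative phosphorylation genes fell, 0 rose and 8 did not pass (camera adjusted p = 2.76e-05, and 0.703 with an estimated correlation), and the 13 protein-coding genes of the mitochondrial genome had a median of −0.595. A larger share of nuclear RNA in the resistant libraries would lower cytoplasmic mRNAs, and alike if they were kept in the nucleus to the same degree. The oxidative phosphorylation list median differed by −0.496 in log2 from that of the cytosolic ribosomal protein list (−0.617 against −0.121). The permutation p = 1e-05 was the smallest possible, across genes, which are not independent replicates. Genes of each list also moved together (estimated correlations 0.316 and 0.871), so this p may be too small. A shift that lowers all cytoplasmic mRNAs alike would not give this difference, but an uneven one was not tested and stays open. For the rise of MALAT1 and NEAT1 a larger share of nuclear RNA may be a source in part. The median of 1363 long intergenic and antisense RNAs was 0.265, with 213 called higher and 108 lower. It lay above the central 95% of matched protein-coding sets (0.051 to 0.234), but far below the log2 rises of MALAT1 (2.24) and NEAT1 (2.82). A shift of that size would leave most of those 2 rises unaccounted for. How far RNAs of this class are kept in the nucleus was not tested, so their median may not give the size of such a shift. Both genes lie on chromosome 11, 1 of the shifted chromosomes. Without the strand setting antisense RNAs cannot be separated from their partners, and no measure of RNA integrity was used here. A response of the resistant cells to growth in the drug remains untested.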
